A study of Chlamydomonas reinhardtii with 34 samples.

How the data were processed

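RNA was sequenced in 34 libraries of Chlamydomonas reinhardtii, 17 of sta6 (CC-4348) and 17 of CC-4349, grown in HSM medium at 25 µmol photons per square metre per second and sampled through nitrogen removal and an acetate boost. The deposited table gave 1 value per gene model and library for 17301 gene models. The unit is not named in the table. The deposited values were taken to be RPKM because of their properties. They are not whole, and each library sums to between 593366 and 711517. In many genes the low values are multiples of a step that depends on the gene and on the library. The aligner was Bowtie, per the submitters' processing notes, which give no version. The genome build, annotation release, counting rule, strand setting and filters are not given in the sources used here. Reads shared by near-identical genes or by overlapping genes on opposite strands cannot be told apart in such a table. Each column was matched to its sample by the name in the sample's description. One column, sta6 at 24 h after the boost, differs from the others in the end of its name.

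Depth was recovered from the low values. In 2625 genes a step worth 1 read was found from their lowest values, pooled over libraries after scaling for relative depth. In these genes 100% of 49780 low values were whole within 0.05 reads. The genes were kept because their lowest values were whole, so this share was largely fixed in advance. The implied totals ranged from 5.72 to 53.9 M reads, so 1 read in a gene model of 1 kb was worth between 0.0186 and 0.175 RPKM and 3 reads between 0.0557 and 0.525 RPKM. These limits cover counting error only, since reads are not independent molecules. Library totals of sta6 were more variable than those of CC-4349, which ranged from 10.7 to 24.1 M. The number of gene models listed at 0 ranged from 792 to 1526. The recovery of relative depth was tested on 5 simulated libraries with known depths. The absolute total, on which the implied totals and the value of 1 read rest, was not simulated. In short gene models 1 read is worth more, and 95 of the genes tested had whole steps with at most 40 reads in their highest library.

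Values were analysed as log2(RPKM + 1), and a fold change on this scale understates the change of low genes. Genes with a mean of at least 1 RPKM over the 34 libraries entered the tests, 14513 in all. Linear models were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend), with Benjamini-Hochberg adjustment. A call was an adjusted p under 0.05 with at least a 2-fold change. The strain difference was fitted with the time point as a block. The other comparisons came from 1 model of 12 strain-by-phase groups, with 22 residual degrees of freedom, as contrasts between phases averaged over the strains or as differences between the strains. Matched time points of the strains deviated together (consensus correlation 0.529). A fit with the time point as a random block was an alternative for starvation and the early boost, but was not run for the differences between the strains. Leaving out this correlation widens the error of a difference between the strains, so the by-strain tests were too strict in this respect. The label-check locus was tested by an exact permutation of strain within time points. Groups, comparisons, the label-check locus and most alternatives were fixed before the data were examined. On simulated data with 14513 genes and 100 changed genes per fold size, the strain difference recovered 99 genes changed by 1.5 on the log2 scale, nitrogen starvation 96, the early boost 97 and the boost by strain 70. At a change of 3 the same comparisons recovered 100, 100, 100 and 97. False calls numbered 3, 1, 1 and 9. The simulated libraries were drawn independently of each other, whereas matched and successive time points of the real libraries are dependent. These figures therefore do not cover the errors that such dependence adds.

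The rule for naming genes asked for members of 24 gene lists, for genes with a symbol and for key genes by symbol. The deposited table does not pair identifiers with names. The reference table, from assembly Chlamydomonas_reinhardtii_v5.5, matched 12666 of 17301 identifiers by locus tag (73.2%) but gave no symbol other than the locus tag, so 0 list members were matched and the list tests were not run. In their place, the 2 called loci with the largest rise and the 2 with the largest fall are named by identifier for the strain difference, nitrogen starvation, the early boost and starvation by strain, and the 1 called locus for the boost by strain. Early starvation and the late boost were not among the comparisons of the rule, and no locus is named for them. For starvation and the early boost they had to have the same sign in both strains, and for the strain difference at 14 or more of 17 time points. No sign rule was applied to the loci of the by-strain comparisons. This replacement was chosen after the values were seen. Checks of gene length or GC content were void because fewer than 80% of genes had a reference entry, and no coordinates are given because the build of the table is not named.

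Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 RPKM, median-of-ratios scaling and quantile normalization between libraries, limma without trend and with robust moderation, other definitions of the phases, the random block, and leaving out each library in turn. Leaving out a replete library leaves 1 in its group, which is then assumed to vary like the other groups. Splits of the same libraries into other groups numbered at most 100 per comparison. Phases were split separately in each strain and also with the time points of both strains kept together. Overlaps are set beside the product of the list sizes divided by the genes tested.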

Results

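Transcript abundance was measured by RNA sequencing in 2 strains of the green alga Chlamydomonas reinhardtii. The sta6 strain (CC-4348) is a starchless mutant that lacks a working small subunit of ADP-glucose pyrophosphorylase, the enzyme that makes the sugar nucleotide used for starch synthesis. CC-4349 was the comparison strain. Cells grown in the light were washed into medium without nitrogen, a treatment under which this alga stores carbon as starch and triacylglycerol. After 48 h without nitrogen the cultures received acetate, here called the boost. Each strain was sampled at 17 time points, namely before the wash, at 0, 0.5, 2, 4, 8, 12, 24 and 48 h without nitrogen, and at 0, 0.5, 2, 4, 8, 12, 24 and 48 h after the boost. The 34 libraries held 1 library per strain and time point. Time points of 1 phase therefore stood in for replicates, and a p-value measured the spread between time points rather than between cultures. The phases were replete (pre-wash and 0 h, n = 2 per strain), early starvation (0.5 to 4 h, n = 3), middle starvation (8 and 12 h, n = 2), late starvation (24 h, 48 h and 0 h after the boost, n = 3), early boost (0.5 to 4 h, n = 3) and late boost (8 to 48 h, n = 4). The read totals recovered from the RPKM values ranged from 5.72 M reads in sta6 at 2 h without nitrogen to 53.9 M in sta6 at 12 h after the boost. In CC-4349 they ranged from 10.7 to 24.1 M.

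The locus fixed for checking the strain labels, Cre03.g188250.t1.1, was low in sta6 at each of the 17 time points. Its mean was 3.11 ± 1.75 RPKM (SD, n = 17) in sta6 and 169 ± 60.1 RPKM (SD, n = 17) in CC-4349. The highest sta6 library held 7.45 RPKM and the lowest CC-4349 library held 100 RPKM. The mean difference on the log2(RPKM + 1) scale was -5.42 ± 1.00 (SD over 17 time points), and the exact two-sided permutation test over 131072 sign flips gave p = 1.5e-05, the smallest value it can give. No library had a level of this locus in the range of the other strain. The locus was tied to the strain by general knowledge of the mutant, because neither the deposited table nor the reference pairs identifiers with gene names.

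The first principal component of the 14513 genes tested held 42.6% of the variance. Its scores rose from -98.1 in CC-4349 and -80.4 in sta6 before the wash to 35.0 and 46.6 at 48 h without nitrogen, and they rose at each step in CC-4349 but fell at 0 h and at 4 h in sta6. The second component held 17.9%, and at each time point its score was higher in CC-4349 than in sta6. The library most similar to each of the 34 libraries was of its own strain. Pearson correlations across genes between the strains at a matched time point lay between 0.904 and 0.938, and genes are not independent replicates in such a correlation.

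**Figure D1:**
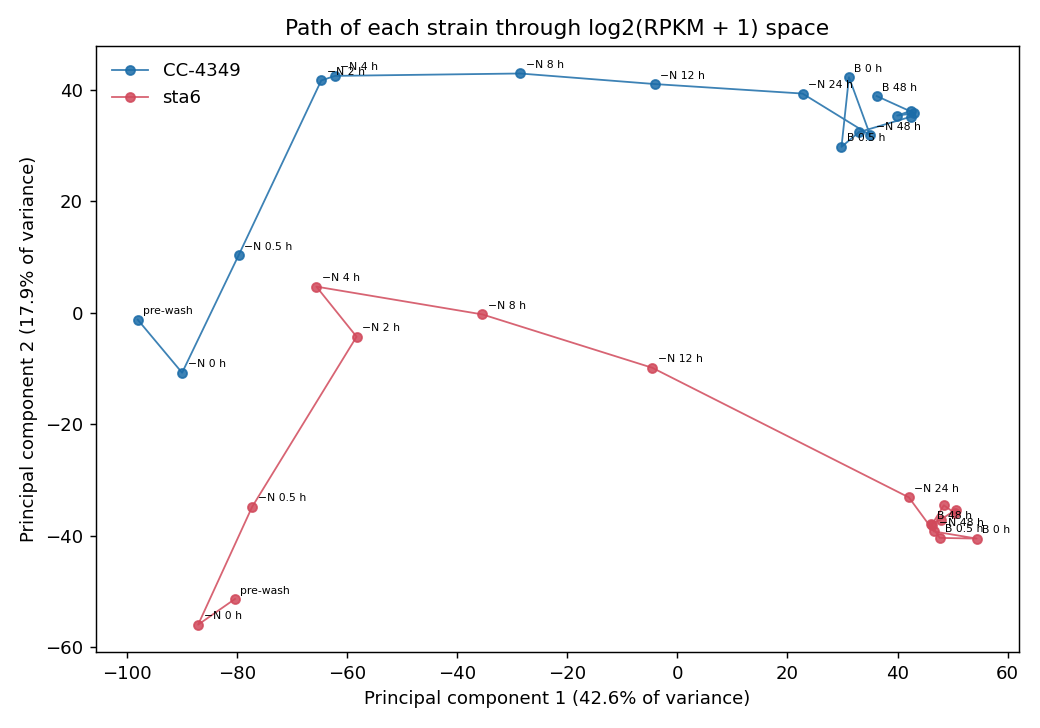
Scores of the 34 libraries on principal components 1 and 2 of log2(RPKM + 1), in arbitrary units, with 1 point per library and lines joining successive time points of a strain. Component 1 (42.6% of variance) runs from the pre-wash libraries at the left to the starved and boosted libraries at the right, and component 2 (17.9%) is higher in CC-4349 than in sta6 at each time point.

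The comparison of the strains over matched time points asked which transcripts differed in the starchless strain whatever the condition. Cre04.g219250.t1.1 was 57.4 ± 39.1 RPKM (SD, n = 17) in sta6, with no library below 24.3 RPKM, whereas no CC-4349 library exceeded 0.0478 RPKM. Cre35.g784050.t1.1 was 72.1 ± 34.1 RPKM (SD, n = 17) in sta6, where the library at 2 h without nitrogen listed it at 0. In CC-4349 it was 9.53 RPKM at 24 h without nitrogen and listed at 0 in each of the other libraries, and it was higher in sta6 at 16 of 17 time points. Few reads lie behind this locus. Its values are whole multiples of a step, which taken as 1 read was worth 3.71 to 35.0 RPKM. On this reading sta6 libraries held 0 to 26 reads and CC-4349 libraries 0 or 1. In a gene model of 1 kb, 1 read was worth 0.0186 to 0.175 RPKM, so the step implies a length of only a few bases. Its RPKM cannot be read as an abundance, and its log2 difference is imprecise. Its place among the largest differences rests on that length. In the other direction, Cre14.g620650.t1.2 was 14.8 ± 18.1 RPKM in sta6 and 816 ± 625 RPKM in CC-4349, lower in sta6 at 17 of 17 time points. Cre16.g656450.t1.1 was 0.423 ± 0.631 RPKM in sta6 and 77.9 ± 35.3 RPKM in CC-4349. In the same order, the log2 differences of these loci were 5.59 (SE 0.198), 5.61 (SE 0.372), -6.17 (SE 0.223) and -5.65 (SE 0.249), on the log2(RPKM + 1) scale used throughout, and the highest limma adjusted p among them was 2.2e-10. In total 846 of 14513 genes passed an adjusted p of 0.05 with at least a 2-fold difference, 400 higher and 446 lower in sta6. Of these, 553 had the same sign at all 17 time points and 215 differed at least 4-fold. The count was 1387 with a pseudocount of 0.1 and 366 with a pseudocount of 5. Successive samples of 1 culture are dependent, so the p-values are too small. With the means of each phase as 6 pairs, 724 genes were called, 705 of them among the 846. At most 40 reads in any library lay behind 15 of the 846.

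Removal of nitrogen was compared as late starvation against replete cells, averaged over the strains. Cre03.g159250.t1.2 rose from 0.511 ± 0.592 RPKM (SD, n = 4) to 550 ± 130 RPKM (SD, n = 6), a log2 change of 8.57 (SE 0.982), and both replete sta6 libraries listed it at 0. Cre10.g442800.t1.2 rose from between 0.168 and 2.31 RPKM in the replete libraries to 615 ± 270 RPKM, a log2 change of 8.19 (SE 0.741). Cre31.g780700.t1.2 fell from 364 ± 123 RPKM to 3.23 ± 3.82 RPKM, a log2 change of -6.81 (SE 0.461). Cre12.g548950.t1.1 fell from 10397 ± 726 RPKM to 329 ± 338 RPKM, a log2 change of -6.52 (SE 0.434), and its fall differed between the strains (log2 difference 5.07, limma adjusted p = 0.000669). In CC-4349 it fell to 23.9 ± 16.4 RPKM and in sta6 to 635 ± 73.0 RPKM (SD, n = 3 each). The highest limma adjusted p of these 4 loci for starvation was 3.5e-08. Calls numbered 4340, or 29.9% of the genes tested, and 4323 of them had the same sign in both strains. As deposited, 2675 were higher and 1665 lower. The median change of all genes was 0.26 on the log2 scale, and the direction of the majority depended on it. With median-of-ratios scaling, which brought that median to 0.01, 1884 were higher and 2264 lower, and with quantile normalization 1896 were higher and 1959 lower. A pseudocount of 5 gave 2174 calls.

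The responses of the strains, which share no library, were alike across genes. Pearson's r between the log2 changes of sta6 and CC-4349 was 0.834. Matched time points deviating together would raise this r and the overlaps that follow. In contrasts per strain from the shared model, 2615 genes were higher in sta6 and 2916 in CC-4349, with 1926 in common against 525 for independent lists. Lower calls numbered 1927 and 1341, with 1050 in common against 178 for independent lists. Only 6 genes were called in opposite directions.

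The extent of the response differed between time points. In CC-4349, 865 genes were at least 2-fold away from the pre-wash library at 0 h, 1292 at 0.5 h, 2828 at 2 h, 2185 at 4 h, 2999 at 8 h and 4761 at 48 h. In sta6 the counts were 1700, 1222, 3405, 3517, 3179 and 4545 at the same times. These counts compare single libraries and carry no test, and the count at 48 h was 2611 in CC-4349 and 2385 in sta6 with a pseudocount of 5. The largest step between successive libraries in the period without nitrogen lay between 0.5 and 2 h in both strains, with 2596 genes in CC-4349 and 2778 in sta6. The step from 0 to 0.5 h was not far below, with 2465 in CC-4349 and 2239 in sta6. The sta6 library at 2 h was the shallowest of all, and other pseudocounts and scalings were not run for these steps. From 12 to 24 h, 1939 genes moved in sta6 and 424 in CC-4349, a difference that was not tested. The fit of early starvation against replete cells called 1758 genes, 1071 higher and 687 lower. With median-of-ratios scaling 673 were higher and 1106 lower, and with quantile normalization 605 and 909. Pseudocounts of 0.1 and 5 gave 2863 and 759 calls.

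**Figure D2:**
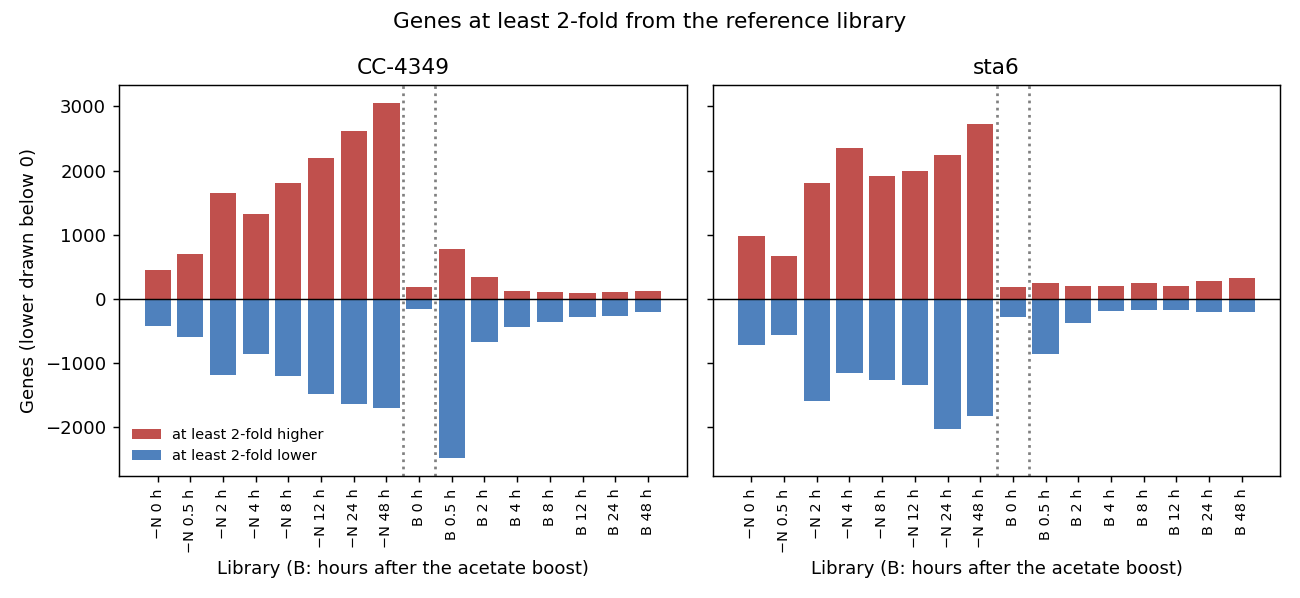
Numbers of genes at least 2-fold higher (upward bars) or lower (downward bars) on the log2(RPKM + 1) scale in each library, out of 14513 tested. Libraries without nitrogen are compared with the pre-wash library, 0 h after the boost with 48 h without nitrogen, and later boost libraries with 0 h after the boost. Each bar compares 1 library with 1 other, so no error is drawn, and dotted lines mark where the reference changes. In CC-4349 the total reaches 4761 at 48 h without nitrogen and 3259 at 0.5 h after the boost.

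Whether starvation acted differently in the 2 strains was tested as an interaction. Cre06.g283950.t1.1 fell in CC-4349 from 1068 ± 122 RPKM (SD, n = 2) to 1.14 ± 0.906 RPKM (SD, n = 3), and the sta6 means were 921 ± 143 RPKM and 549 ± 546 RPKM. It fell in sta6 as well, to 133 RPKM at 12 h without nitrogen. The late sta6 libraries were uneven, with 1180 RPKM at 24 h, 245 at 48 h and 223 at 0 h after the boost. The difference of the log2 changes was 7.86 (SE 0.823). Cre07.g346850.t1.1 went from 216 ± 59.4 to 1.47 ± 1.02 RPKM in CC-4349, and no sta6 library exceeded 0.781 RPKM, so its difference of 6.07 (SE 0.933) rests on CC-4349. Cre06.g263200.t1.1 went from 0.154 ± 0.111 to 82.2 ± 43.9 RPKM in CC-4349 and from 1.39 ± 1.97 to 0.615 ± 0.213 RPKM in sta6, a difference of -6.32 (SE 0.706). Cre06.g254900.t1.2 went from 0.0844 ± 0.0630 to 79.9 ± 26.0 RPKM in CC-4349 and stayed at or below 0.0865 RPKM in each sta6 library, a difference of -6.23 (SE 0.728). The highest limma adjusted p of these loci was 0.000207. In total 415 genes were called, 139 with a higher and 276 with a lower change in sta6. The median of all genes was -0.12. With median-of-ratios scaling the calls were 153 and 202, and with quantile normalization 171 and 197. The count was 265 among genes with a mean of at least 5 RPKM, 251 without 0 h after the boost in the late group and 171 without the 0 h and boost 0.5 h libraries of both strains. With a replete group of 2 libraries per strain the count also moved with single libraries, to 222 without the CC-4349 library at 0 h, 248 without the sta6 library at 0 h and 754 without the sta6 pre-wash library.

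**Figure D3:**
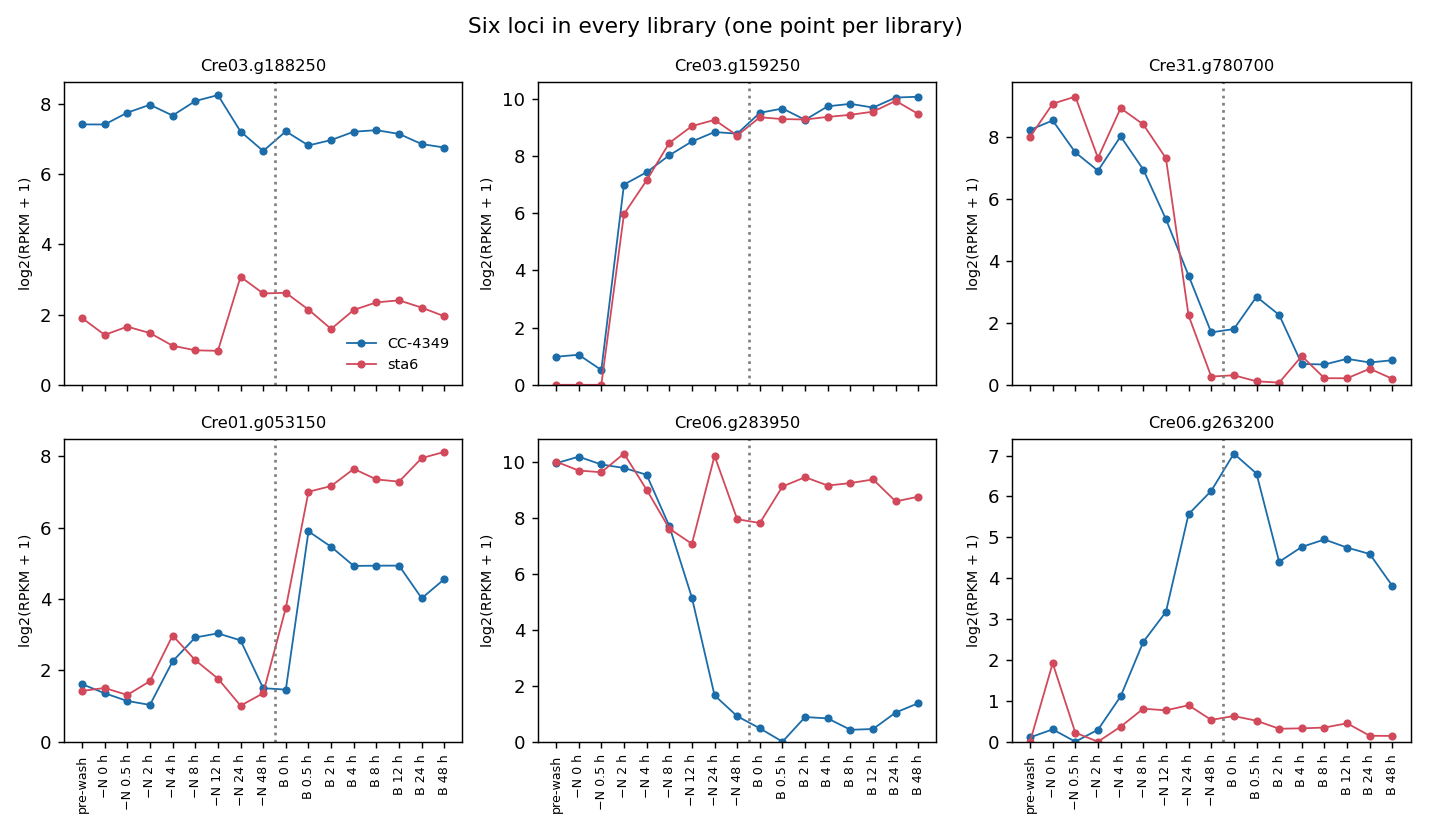
Abundance of 6 loci as log2(RPKM + 1) in each of the 17 libraries of CC-4349 and sta6, with 1 point per library, time points evenly spaced in order and a dotted line before 0 h after the boost. Cre03.g188250 is lower in sta6 in each library, Cre03.g159250 rises and Cre31.g780700 falls in both strains, and Cre01.g053150 rises after the boost. Cre06.g283950 falls to 2.15 RPKM at 24 h without nitrogen in CC-4349. In sta6 it falls to 133 RPKM at 12 h without nitrogen and is higher in the later libraries. Cre06.g263200 rises in CC-4349 and stays at 2.78 RPKM or less in sta6.

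The early boost was compared with late starvation to ask which transcripts moved within 4 h of acetate. Cre01.g053150.t1.1 rose from 3.25 ± 2.53 to 43.7 ± 14.6 RPKM in CC-4349 and from 5.02 ± 6.47 to 157 ± 38.0 RPKM in sta6 (SD, n = 3 each), a mean log2 change of 4.37 (SE 0.364). Cre17.g705700.t1.1 rose from 2.89 ± 2.01 to 20.3 ± 10.4 RPKM over both strains (SD, n = 6 each), a log2 change of 2.47 (SE 0.307). Cre13.g580000.t1.1 fell from 313 ± 252 to 42.5 ± 18.3 RPKM, a log2 change of -2.59 (SE 0.412). Cre06.g293100.t1.1 fell from 33.7 ± 32.5 to 4.20 ± 2.63 RPKM, a log2 change of -2.36 (SE 0.434). The highest limma adjusted p of these 4 loci was 0.0013. The calls numbered 186, of which 29 were higher and 157 lower, and 185 had the same sign in both strains. The median of all genes was -0.12. With median-of-ratios scaling 51 were higher and 82 lower, and with quantile normalization 49 and 76. The count was 535 and 50 with pseudocounts of 0.1 and 5, 101 with 2 h and 4 h alone as the early boost, 367 with 48 h and 0 h after the boost as the baseline, 103 without the 0 h and boost 0.5 h libraries of both strains and 129 with matched time points as a random block. With 0 h after the boost counted as early boost 2 genes were called, and of the loci above 3 were not among them. Their log2 changes kept their sign and were 1.93 for Cre17.g705700.t1.1 (limma adjusted p = 0.059), -1.90 for Cre13.g580000.t1.1 and -1.84 for Cre06.g293100.t1.1 (both limma adjusted p = 0.13). The count was 105 without the sta6 library at 48 h, 123 without sta6 at 0.5 h after the boost, 280 without CC-4349 at 24 h and 287 without CC-4349 at 4 h after the boost. No culture without acetate was sampled at these times, so the boost and elapsed time cannot be separated.

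The libraries at 0.5 h after the boost, like those at 0 h without nitrogen, held fewer genes at 1 RPKM or more than the others (12858 to 13093 against 13488 to 14300). In CC-4349, 3259 genes were at least 2-fold away from 0 h at 0.5 h after the boost, 778 higher and 2481 lower. In sta6 the number was 1101, with 243 higher and 858 lower. With a pseudocount of 5 the numbers were 1032 in CC-4349 and 359 in sta6, and with 0.1 the number in sta6 was 2118. At 8 h it was 475 in CC-4349 and 423 in sta6, and the library at 0 h after the boost was 333 and 459 genes away from the one at 48 h without nitrogen. The difference between the strains at 0.5 h has no replicate and was not tested. The strains' log2 changes in the early boost correlated across genes with r = 0.579, a value that matched time points deviating together would raise.

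Late boost libraries differed from late starvation in 84 genes, 47 higher and 37 lower, all with the same sign in both strains. With median-of-ratios scaling 49 were higher and 24 lower. The majority turned with a pseudocount of 0.1 (57 higher and 86 lower, 143 in all), without CC-4349 at 24 h without nitrogen (44 and 51) and without sta6 at that time (46 and 52). The count was 33 with a pseudocount of 5 and 54 among genes with a mean of at least 5 RPKM. In the limma interaction test of the early boost, 374 of 14513 genes had an unadjusted p under 0.05, fewer than expected by chance alone. This test leaves out the pairing of matched time points, which deviated together, and is too strict in this respect. A low count therefore does not show that the strains responded alike. After adjustment 1 gene was called. This gene, Cre03.g204500.t1.2, went from 18.2 ± 9.11 to between 1.93 and 3.30 RPKM in CC-4349 and from 0.542 ± 0.194 to 0.464 ± 0.0389 RPKM in sta6 (SD, n = 3 each), a difference of 2.22 (SE 0.336, adjusted p = 0.0075). The call was lost without the CC-4349 library at 0.5 h after the boost (difference 2.05, adjusted p = 0.054), with a pseudocount of 0.1 (2.47, adjusted p = 0.31), without the 0 h and boost 0.5 h libraries of both strains (2.07, adjusted p = 0.16) and with 0 h counted as early boost (1.05, adjusted p = 1.00), all by limma. With a mean of at least 5 RPKM the gene did not enter the test. Some other alternatives, given further below, raised the count of called genes above 1.

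Changes on starvation and after the boost were compared across genes, which are not independent replicates. With separate libraries in each comparison (24 h for starvation, 48 h and 0 h after the boost as the baseline of the boost), Pearson's r was -0.0214 in sta6 and 0.0479 in CC-4349. When both comparisons used the same late starvation libraries, r was -0.103 with a covariance of -0.0437 in sta6 and -0.0357 with a covariance of -0.0164 in CC-4349. Simulated libraries without effects between phases gave a mean r of -0.446 and a covariance of -0.0442 when the late libraries were shared. They were drawn independently with the spread within phases, which includes any real change between the time points of a phase. The simulation therefore does not isolate what sharing libraries adds, and no conclusion is drawn from its nearness to the sta6 covariance.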

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

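No test in this part was chosen after its result was seen, but the loci named, apart from the label-check locus, were, and so was the rule by which the scaling test below counts for neither explanation.

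Starvation acted differently in sta6 and CC-4349 in 415 genes by the limma interaction test, with more lower (276) than higher (139) changes in sta6. The share of higher calls rose from 33.5% to 46.5% with quantile normalization and to 43.1% with median-of-ratios scaling, so lower calls stayed the majority. Both scalings bring the median of all genes from -0.12 to near 0, which moves calls towards the higher side whatever the cause. Scaling and a real imbalance therefore cannot be told apart. A single library does not account for it, as the share stayed at or below 40.2% whichever library was left out. The real split gave 415 calls and the highest of the other splits 2175 (3 of 16 swaps of strain within time points were as large, and 16 are too few for a share under 0.05), where the strains were swapped at all late starvation time points so that the contrast holds the strain difference. A biological difference between the strains stays open and was not tested apart from scaling.

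Several named loci differed between the strains in their response to starvation by the same test. The log2 differences, sta6 minus CC-4349, were 7.86 for Cre06.g283950.t1.1, 6.07 for Cre07.g346850.t1.1, 5.07 for Cre12.g548950.t1.1 and 1.49 for the label-check locus Cre03.g188250.t1.1. They were -6.32 for Cre06.g263200.t1.1, -6.23 for Cre06.g254900.t1.2, -3.57 for Cre03.g204500.t1.2, -2.36 for Cre16.g656450.t1.1 and -1.98 for Cre04.g219250.t1.1. At several of these loci 1 strain was low in each of its 17 libraries, so that the difference rests on the other. In sta6 the highest value was 0.781 RPKM at Cre07.g346850.t1.1, 2.78 at Cre06.g263200.t1.1, 0.0865 at Cre06.g254900.t1.2, 0.767 at Cre03.g204500.t1.2 and 2.26 at Cre16.g656450.t1.1, and in CC-4349 it was 0.0478 RPKM at Cre04.g219250.t1.1.

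The limma interaction test of the early boost called 1 gene, Cre03.g204500.t1.2, with a log2 difference of 2.22. In 32 swaps of strain within time points, 11 gave at least 1 call, the highest of the others being 3038 for the swap at all early boost time points, a split that holds the strain difference, so chance cannot be excluded for this gene.

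Within the 4 late boost libraries of sta6, 4 values stood apart. The library at 24 h after the boost held 13786 genes at 1 RPKM or more against 13844 to 13848 in the others, and its lower quartile was 1.61 RPKM against 1.68 to 1.69 RPKM. Cre31.g780700.t1.2 was 0.431 RPKM at 24 h and 0.145 to 0.159 RPKM in the others. Cre07.g346850.t1.1 was 0.0165 RPKM at 48 h and listed at 0 in the others, and any lone value above 0 gives the largest gap possible, so this one carries no information. The other 3 values belong to the library at 24 h, the one whose column name ends differently, and whether it was prepared differently was not tested. They are not separate signs. The count of genes at 1 RPKM and the lower quartile both describe the low genes of that library. The value of Cre31.g780700.t1.2 lies near the counting limit there, where 3 reads in 1 kb are worth 0.234 RPKM. Chance gives such a gap in about 5% of groups, and 4 of the 49 groups of 4 values tested had one.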

How the results depend on the processing

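The alternative without the 0 h and boost 0.5 h libraries, those for the label-check locus, and those for the strain-only loci, time point counts and strain agreement were chosen after seeing the data. The label-check difference stayed past its threshold in each alternative run, from -5.86 with a pseudocount of 0.1 to -4.38 with a pseudocount of 5, and from -5.50 to -5.30 when a time point was left out. The direction of most calls turned for starvation with median-of-ratios scaling (45.4% higher) and quantile normalization (49.2%), for early starvation with both (673 of 1779 and 605 of 1514 higher) and with a pseudocount of 5 (49.5%), and for the late boost with a pseudocount of 0.1 (39.9%) and without either library at 24 h without nitrogen. It turned for the early boost with 0 h counted as early boost (2 higher and 0 lower), and for the strain difference, near an even split, with quantile normalization (51.0%), without the time point block and with the time points before the boost alone. Of 812 alternative values for the loci named in the comparisons, 805 kept their direction and side of the threshold and 7 kept their direction but were no longer past it. Apart from the label-check locus, these loci were picked as the largest called changes, and most of the alternatives left out 1 library. The share therefore says little about other genes. The 7 belong to loci of the early boost and the boost by strain. Call counts moved with the pseudocount, the filter, the phase definitions and single libraries. With a pseudocount of 0.1 they were 1387 for the strain difference, 2863 for early starvation, 535 for the early boost, 143 for the late boost and 0 for the boost by strain (limma, 344 genes at an unadjusted p under 0.05). With 5 they were 366 for the strain difference, 2174 for starvation, 759 for early starvation, 50 and 33 for the early and late boost and 3 for the boost by strain. A mean of at least 5 RPKM gave 265 for starvation by strain, 54 for the late boost and 0 for the boost by strain (limma, 235 unadjusted), with 9737 genes tested. No filter gave 6 for the boost by strain. Without 0 h after the boost in the late group, starvation by strain had 251 calls. Counting 0 h as early boost left 2 calls for the early boost and 0 for the boost by strain (limma, 209 unadjusted). The early boost had 367 calls with 48 h and 0 h as the baseline and 101 with 2 h and 4 h alone. Without the 0 h and boost 0.5 h libraries the counts were 171 for starvation by strain, 103 for the early boost and 0 for the boost by strain (limma, 509 unadjusted). Each of the unadjusted counts given here was below the number expected by chance alone. The test of the boost by strain leaves out the pairing of matched time points, so these low counts do not show alike responses. The cause of the shifts in call counts was not tested. The random block of matched time points gave 4302 calls for starvation and 129 for the early boost, of which 12 were higher and 117 lower. Leaving out 1 library at a time gave 825 to 874 calls for the strain difference, 4075 to 4721 for starvation, 1380 to 2589 for early starvation, 222 to 754 for starvation by strain, 105 to 287 for the early boost, 59 to 98 for the late boost and 0 to 8 for the boost by strain. The planned gene list tests, with preset or estimated correlation, were not run because no list member could be matched. Depth limits low genes most in sta6 at 2 h without nitrogen, where 3 reads in 1 kb are worth 0.525 RPKM.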

Other observations

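The tests of strain-only loci and of the libraries just after the wash and the boost were chosen after the results were seen, as were the splits with matched time points.

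Some loci were seen in 1 strain only (at least 1 RPKM in each of its libraries and a mean in the other strain under 1% of it), 23 in sta6 and 13 in CC-4349, or 8 and 5 with at least 5 RPKM, and 22 in CC-4349 with a mean under 2%. Of the 23, 8 lay within 15 consecutive gene models that include Cre04.g219250.t1.1, against at most 4 in 1000 random sets. Depth argues poorly for this pattern, since 13 loci were missing in sta6, the strain with the larger recovered total (415 against 295 M reads). Neighbouring gene models were both strain-only in 4 and 2 pairs, more than in any of 10000 random sets (highest 2 and 1, permutation p = 0.0001 for each, the smallest these sets can give), which is consistent with segments that are absent or rearranged in 1 strain's genome, although random sets do not allow for neighbours that are expressed together. Strain variants that keep reads from aligning cannot be told apart from absence, because 8.33% of the loci were at 0 in each library of the other strain and similar copies elsewhere could supply the remaining reads.

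The libraries at 0 h without nitrogen and at 0.5 h after the boost held fewer genes at 1 RPKM or more than the other 30, in both strains. They held 12858 to 13093 such genes against 13488 to 14300, and their lower quartiles were 0.935 to 1.06 RPKM against 1.32 to 2.13 RPKM. Depth is argued against by the shallowest library, which held 13950 such genes, and a few dominant genes by 5 other libraries with a larger share of signal in their top 10 genes. The changes at each step were alike between the strains. Across genes r was 0.610 over the wash and 0.506 over the first 0.5 h of the boost. Matched time points deviating together would raise both values. A single response common to the wash and the boost in both strains is argued against as the whole cause by the lowest correlation between them. The changes over the wash in CC-4349 and over the first 0.5 h of the boost in sta6 correlated across genes with r = -0.0294. The other pairings of wash and boost gave 0.0665, 0.368 and 0.245. As a reference, wash changes against those from 24 to 48 h without nitrogen gave r from -0.117 to 0.0760. Pairings with the CC-4349 boost lay above this range and those with the sta6 boost within it. Each r rests on single libraries. Genes at least 2-fold lower in both numbered 37, 141, 14 and 97 in the pairings of sta6 wash with sta6 and CC-4349 boost and of CC-4349 wash with the same, against 42.5, 123, 24.9 and 72.0 for independent lists, and genes higher in both numbered 57, 395, 12 and 66 against 16.4, 52.6, 7.43 and 23.8, so that a partly shared response stays open, as do RNA quality and a rapid response to each treatment, which were not tested.

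The locus Cre01.g053150.t1.1, which rose after the boost, was 12.5 RPKM in sta6 at 0 h after the boost and 1.56 RPKM at 48 h without nitrogen. In CC-4349 it was 1.75 and 1.83 RPKM at these times. At 24 h without nitrogen the nearest library was at 2 h after the boost in CC-4349 (r = 0.980) and at 4 h after the boost in sta6 (r = 0.975).

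The recovered read totals of CC-4349 at 4 h without nitrogen and at 48 h after the boost were equal in all digits recovered, at 17.7 M reads. The next closest of the 561 pairs of libraries differed by 0.0171%. The profiles of these libraries differed (r = 0.897 across genes on the log2 scale), so they were kept as separate libraries. Whether 1 of them was scaled with the total of the other was not tested, and all its RPKM values would then be off by 1 factor. The sums of RPKM were 635753 and 674976, within the 593366 to 711517 of all libraries, and leaving out either library moved no count by more than 1.5 times except the boost by strain, which had 4 calls without the library at 4 h.

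Other splits of the same libraries were fitted for each count. For the strain difference 1 of 100 draws of swaps within time points, the real one, gave at least 846 calls, and the highest other gave 0. Swaps put any lasting difference between the cultures into the spread, so few calls were to be expected of them. The counts show a lasting difference between the 2 sets of libraries, and a chance difference between cultures is not excluded. When the phases were split separately in each strain, the highest other of 100 splits gave 2502 calls for starvation (real 4340), 2436 for early starvation (real 1758), 118 for the early boost (real 186) and 0 for the late boost (real 84). Matched time points deviate together, which such splits partly cancel. With the time points of both strains kept together, the late boost had 1 of 35 splits with at least 84 calls, the real one, and 26 as the highest other. Successive samples of a culture are ordered in time, and any drift with elapsed time favours the split in time order. Such splits cannot tell drift from an effect of the boost, and no conclusion on chance is drawn from them. For starvation, early starvation and the early boost these splits number 10 each, too few for a share under 0.05, and the highest others gave 2502, 2436 and 84. The split with 2436 calls set 2 h and 4 h against pre-wash, 0 h and 0.5 h, and was the only other split of early starvation, among the 10 and among the 100, with at least as many calls as the real one (2 of each, the real one included).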
